A study of Mus musculus with 5 samples.

How the data were processed

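Poly-A selected RNA from primary epididymal adipocytes of C57BL/6N mice on a high-fat diet was made into Illumina TruSeq libraries and sequenced on a HiSeq4000, per the labels' protocols. The design text describes adipocyte-specific Prmt1 knockout mice and wild type mice, and the sample titles call the groups Prmt1 FKO (2 samples) and Prmt1 f/f (3 samples). Groups and replicate numbers were taken from the titles, and the columns of the table were matched to samples through the sample descriptions.

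The authors deposited 1 table of 36780 rows for the whole series, with RefSeq transcripts as rows. HISAT2 2.1.0, HISAT, Bowtie2 and StringTie 1.3.4d and the genome build mm10 are named in the submitters' processing notes, with no role or order. The deposited estimated counts are whole numbers per transcript and sample with no scaling between samples, per the file headers and the values. In transcripts with few reads the deposited count exceeded the count implied by the FPKM by 0.441 to 0.452 on average and by 0 to 1 (within 0.02) in 100% of rows, so the counts behave like abundance estimates rounded up. The deposited FPKM values are fragments scaled by transcript length and library size, per the file headers, and were used for 1 alternative. Coordinates are those of the table, 1-based, on mm10. Of 24531 gene identifiers, 24461 matched a RefSeq table of GRCm38.p6, and 63.5% of gene starts were equal to it.

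The single row that names no gene, whose cells are empty, was left out, which left 36779 transcripts of 24531 genes, and 0 columns of values per sample were left unused. The table can split counts between overlapping or near-identical genes, and overlaps were counted from its coordinates with no use of strand. Counts were summed per gene identifier. Total estimated counts per sample were 43580154 to 57016997, and 15660 to 16649 genes had a count. Intervals on ratios of counts (95%, exact binomial) and the floor of 3 counts cover counting error only. Every pair of libraries within a group differed by more than sampling noise, with a median chi-square per gene of 3.71 to 15.5 where noise alone gives 0.455, so no library was counted as a copy of another.

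Differential expression was tested in R 4.3.3 with edgeR 4.0.16, by the quasi-likelihood test on all 5 samples with genotype as the sole term, TMM factors and the filterByExpr filter, at a Benjamini-Hochberg adjusted p of 0.05. The TMM factors were 1.035, 1.036 and 1.123 in f/f and 0.9004 and 0.9215 in FKO. Standard errors were taken as the log2 fold change divided by the square root of F. Fold changes are model estimates of FKO over f/f, with CPM scaled by TMM. The biological coefficient of variation was 23%. Gene sets were tested with camera (limma 3.58.1, preset correlation 0.01) on log CPM with a prior count of 2, in lists with at least 5 tested genes, with an estimated correlation and fry beside it. The 33 lists, the groups, the tests, the alternatives listed last and the rule for named genes were set before the data were examined. Transcript use was tested with edgeR's diffSpliceDGE on 10759 transcripts of 3997 genes.

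The rule named Prmt1 and its family, the 10 largest rises and 10 largest falls among called genes with no overlap between groups and a mean of at least 1 CPM (gene models with Gm, Rik or LOC names left out), up to 4 genes per list with the smallest p, and up to 5 genes with the smallest p for transcript use. Not every gene that meets the rule is reported here. Genes named outside the rule are marked as chosen after their values were seen.

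The gene test, the camera list test and the transcript use test were tried on simulated data. The alternative tools, fry, the exact intervals, the sums of gene copies and the permutation tests were not. For the FKO against f/f gene test, 200 genes were changed among about 14314 genes drawn from the real means and library sizes. The dispersion was assumed and was the same for every gene, so recovery in more variable genes was not tested. Only these 200 genes were changed, whereas 25.4% of the genes tested in the data were called. The adjusted threshold is stricter when few genes change, so recovery and false calls can differ in the data. The test recovered 5.97% of 67 genes changed 1.5-fold, 34.3% of 67 changed 2-fold and 100% of 66 changed 4-fold, with 2.11% false calls. In the FKO against f/f list test on 14338 simulated genes, the shifted list was called and 0 of 29 other lists were. The simulated genes varied independently, so this does not show how often lists whose genes vary together are called falsely. For FKO against f/f transcript use in 3942 simulated genes, also with an assumed dispersion, 69.5% of 200 genes with a 4-fold change were recovered, and 9.74% of calls were false.

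Alternatives were RLE and upper-quartile factors, no filter and a stricter filter on counts (10 counts in each group mean and 1 CPM), the replicate number as a block, each sample left out in turn, limma-voom, limma on log2(FPKM + 1), DESeq2 1.42.0, tests per transcript row, a 2-fold threshold, and for transcript use a filter of 1 CPM and 10% of the gene's counts. Library size alone was added after the data were seen.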

Results

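Messenger RNA was measured in primary adipocytes from the epididymal fat of mice on a high-fat diet for 12 weeks. PRMT1 is the main enzyme that places asymmetric dimethylation on arginine residues of histones and RNA binding proteins. There were 3 libraries from floxed mice that keep the gene (Prmt1 f/f) and 2 from mice that lack Prmt1 in adipocytes (Prmt1 FKO). Estimated counts summed to 43580154, 56737479 and 57016997 in f/f replicates 1 to 3, and to 49981062 and 45665542 in FKO replicates 1 and 2. At these depths 3 counts, the upper limit that a count of 0 allows, correspond to between 0.0526 and 0.0688 CPM (counts scaled to a common library size). Scd1, the fatty acid desaturase with the largest share of the counts, took 6.84%, 6.92% and 4.29% of them in f/f and 3.13% and 2.63% in FKO; it was singled out after its values were seen. The first principal component held 67.2% of the variance and separated the f/f libraries (-38.0, -45.4 and -61.1) from the FKO libraries (74.0 and 70.5). Correlations of log CPM across genes were between 0.9727 and 0.9825 within a group and between 0.9279 and 0.9443 across groups. The labels do not say that the libraries came from separate animals, so p-values measure the spread between these libraries only.

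The first comparison checked the deleted gene and the rest of its enzyme family. Prmt1 (gene 15469, mm10 chromosome 7, 44976755 to 44986420) was 1.58-fold lower in FKO, at 34.1, 29.4 and 32.3 CPM in the 3 f/f libraries and 21.0 and 19.3 CPM in the 2 FKO libraries. Its log2 fold change was -0.66 (SE 0.14, edgeR quasi-likelihood test, adjusted p = 0.0171), and FKO held 20.2 ± 1.17 CPM (SD, n = 2) against 31.9 ± 2.39 CPM in f/f (SD, n = 3). Of the 8 family members tested, Prmt6 rose from 6.68 to 11.1 CPM (log2 fold change 0.74, edgeR adjusted p = 0.0202) and Prmt9 from 20.3 to 30.2 CPM (0.57, edgeR adjusted p = 0.0308). Prmt2, Carm1 and Prmt5 had log2 fold changes of -0.39, 0.46 and 0.31 and did not pass the edgeR test (adjusted p = 0.0746, 0.0977 and 0.141); Prmt2 passed with upper-quartile factors (0.0336), with library size alone (0.0184) and on the FPKM scale (0.0232). Prmt3 and Prmt7 were at 0.07 and 0.10, also short of the threshold. Other scalings put both below 0, along with a lower median of all genes (-0.17 with upper-quartile factors, -0.27 with library size alone and -0.14 on the FPKM scale, against -0.048). Adjusted over the list alone, 2 members rose and 2 fell, and the family as a set was not called by camera (median log2 fold change 0.20, adjusted p = 0.357). That median became -0.016 with library size alone, but lay 0.25 above the median of all genes before and 0.26 after, and it became -0.0055 on the FPKM scale. The exons removed are not given in the sources used here, so the Prmt1 counts can include reads from outside the deleted part. They can also include reads from other cell types, which an adipocyte-specific knockout does not target. Markers of several such cells were lower in FKO (median log2 fold change -1.38 for macrophages and -2.08 for mesothelium). The Prmt1 difference therefore cannot be assigned to adipocytes alone. The Prmt1 call ended without FKO replicate 1 (log2 fold change -0.72, edgeR adjusted p = 0.115) or without FKO replicate 2 (-0.60, edgeR adjusted p = 0.161), and over all alternatives its adjusted p lay between 0.000719 and 0.161. The Prmt6 call ended without FKO replicate 1 or 2 (edgeR adjusted p = 0.153 and 0.114) with library size alone (0.0758) and on the FPKM scale (0.0816), within a range of 0.00072 to 0.153. The Prmt9 call ended without f/f replicate 2 or FKO replicate 1 or 2 (edgeR adjusted p = 0.0608, 0.204 and 0.156), with upper-quartile factors (0.0553), with library size alone (0.094) and on the FPKM scale (0.112), among other settings, within a range of 0.00538 to 0.204.

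**Figure D1:**
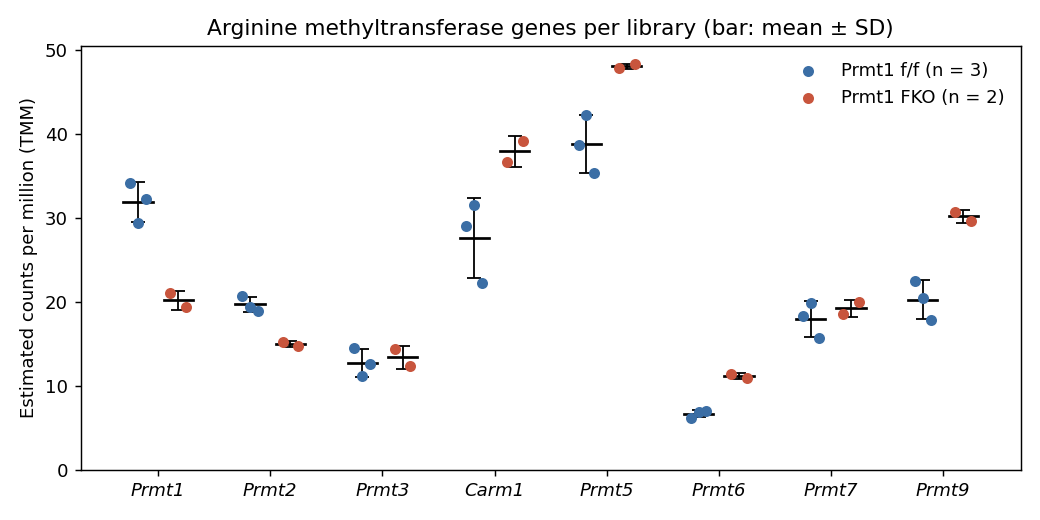
Estimated CPM, scaled with TMM, of 8 arginine methyltransferase genes in each library, with points for libraries and bars for the mean ± SD of 3 f/f and 2 FKO libraries. Prmt1 sat at 29.4 to 34.1 CPM in f/f and at 19.3 and 21.0 CPM in FKO.

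The second comparison asked which genes differed between FKO and f/f adipocytes. Apart from Cbr3, the genes with the largest rises named here had f/f means below 1 CPM. Slc22a12, a urate transporter (chromosome 19, 6535856 to 6543070), had 2 counts over the 3 f/f libraries and 1849 over the 2 FKO libraries, a ratio of 1780 (95% interval 493 to 14700). Aadac, an esterase of the endoplasmic reticulum (chromosome 3, 60031788 to 60040157), went from 2 to 1617 counts, a ratio of 1560 (431 to 12900). Cbr3, a carbonyl reductase (chromosome 16, 93683219 to 93690991), rose 70.7-fold from 4.34 ± 0.89 CPM (SD, n = 3) to 307.5 ± 89.0 CPM (SD, n = 2). Vipr2, a receptor for vasoactive intestinal peptide, rose 117-fold to 44.1 CPM. Acox2, a peroxisomal oxidase of branched acyl-CoA, rose 140-fold to 8.51 CPM, Eef1a2, a translation elongation factor of muscle and neurons, rose 266-fold to 8.59 CPM, and Prrt1 rose 46.5-fold to 15.4 CPM. Hapln4 and Fndc5 rose 42.9-fold and 30.1-fold to 3.72 and 2.93 CPM.

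Sfrp5, a secreted Wnt-binding protein (chromosome 19, 42197971 to 42202252), fell from 341.3 ± 204 CPM in f/f (SD, n = 3) to 1.25 ± 0.51 CPM in FKO (SD, n = 2), 273-fold lower. Ranbp3l fell 46.7-fold from 4.92 CPM, Cux2, a homeobox factor, fell 41.2-fold from 2.94 CPM, and Tfr2, a transferrin receptor, had 3 counts in FKO against 512 in f/f (ratio 0.0113, 95% interval 0.00232 to 0.0332). Wisp2, a secreted matricellular protein, and Akr1b7, an aldo-keto reductase, fell 82.4-fold and 68.8-fold, from means with wide spread between f/f libraries (6.82 ± 6.92 and 9.68 ± 9.39 CPM, SD, n = 3). Crisp1, a secretory protein of the epididymis, had 367 counts in f/f and 0 in FKO, at least 63.4-fold lower against a floor of 3 counts over the group, and 283 of those counts were in 1 f/f library. With limma-voom the calls of Akr1b7, Wisp2, Crisp1 and Cux2 ended (adjusted p = 0.475, 0.173, 0.0925 and 0.0633), as they did on the FPKM scale (0.141, 0.0918, 0.169 and 0.0924); that of Akr1b7 also ended with no filter (0.052) and that of Crisp1 without f/f replicate 3 (0.057). Npcd (0 counts in FKO, at least 97.1-fold lower), Sap18b (59.3-fold lower) and Il11ra2 (0 counts in FKO, at least 59.6-fold lower) are uncertain, because they overlap or nearly copy other genes of the table. The table places Sap18b within Sap18, whereas RefSeq places it on another chromosome, and the counts of the pair summed to 84.4 ± 8.77 CPM in f/f (SD, n = 3) and 82.8 ± 1.13 CPM in FKO (SD, n = 2). Npcd, with a mean of 3.52 CPM in f/f, spans Nptxr and Cbx6, and these 3 summed to 33.5 ± 3.99 CPM in f/f (SD, n = 3) and 34.7 ± 5.23 CPM in FKO (SD, n = 2). Il11ra2 and its paralog Il11ra1 together fell from 50.2 ± 7.10 CPM (SD, n = 3) to 28.1 ± 3.49 CPM (SD, n = 2), with an edgeR adjusted p = 0.016 for the sum.

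Among 14492 genes tested, 1730 rose and 1944 fell in FKO, together 3674 or 25.4% (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Of these, 758 rose and 1374 fell by at least 2-fold. The groups did not overlap in 8557 genes (59% of those tested), where chance gives 20%. Of the called genes, 93 of the fallers had 0 counts in both FKO libraries and 6 of the risers had 0 counts in all f/f libraries. Genes that overlap another gene of the table made up 1103 of the 3674 called genes (30%) and 4552 of the 14492 tested (31.4%). Each gene was taken as 1 span per chromosome. A gene with distant copies therefore counts as overlapping all that lies between them, and these shares can be too high. The number called was 909 without FKO replicate 1 and 1022 without FKO replicate 2, each of which leaves 1 library in the group; of 135 called genes that the selection rule picked or that were singled out, 52 lost the call in each case. Among named genes, Carm1, Cidea, Cpt1b, Mpc1, Me1, Pfkp, Nampt, Ccl6, Ifi27l2a, Tagln and Mb overlap another gene of the table, which can share their counts. For Ccl2, Pdk2, Dpp4 and Rpl35 the only tested partner was Mir684-1, whose joined span covers genes far apart, so no true overlap is shown. The share of called genes that rose was 47.1%, against 35% with upper-quartile factors, 26.1% with library size alone and 28.8% on the FPKM scale, which moved the median log2 fold change of all genes from -0.048 to -0.17, -0.27 and -0.14.

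**Figure D2:**
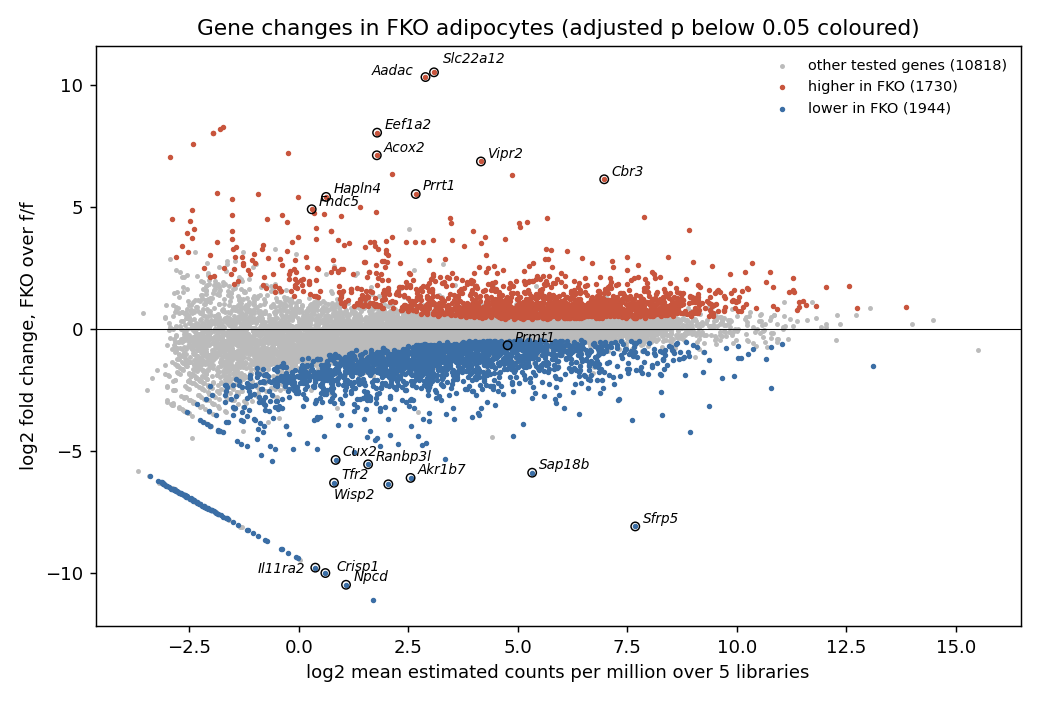
Log2 fold change of FKO over f/f against the log2 mean CPM of each of 14492 tested genes, with 1730 called higher in red, 1944 called lower in blue and named genes circled. Genes with 0 counts in FKO form the line at the lower left, where the fitted fold change is set by the prior count and is no measure of size.

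Genes of mitochondrial energy metabolism rose together in FKO. Of 23 genes of the TCA cycle and pyruvate use, 19 rose and 0 fell (20 and 1 adjusted over the list alone), with a median log2 fold change of 1.12 (camera adjusted p = 2.83e-08, but adjusted p = 0.566 with an estimated correlation). Mpc1, a subunit of the mitochondrial pyruvate carrier, rose 3.09-fold, and Dlat and Pdk2 of the pyruvate dehydrogenase system rose 2.44-fold and 2.35-fold. Of 27 genes of fatty acid oxidation, 21 rose and 0 fell (23 and 0 adjusted over the list alone), with a median of 1.01 (camera adjusted p = 1.57e-11, but adjusted p = 0.566 with an estimated correlation). Cpt1b, the muscle and brown fat form of carnitine palmitoyltransferase, rose 20.3-fold from 3.75 ± 1.20 CPM (SD, n = 3) to 76.5 ± 28.9 CPM (SD, n = 2). Ehhadh of peroxisomal oxidation rose 7.86-fold, Hadha of the mitochondrial trifunctional protein 3.48-fold and Slc25a20, the carnitine carrier, 2.48-fold. Of 54 nuclear genes of the respiratory chain, 39 rose and 0 fell (44 and 0 adjusted over the list alone), with a median of 0.69 (camera adjusted p = 5.56e-13, but adjusted p = 0.566 with an estimated correlation). Uqcrc1, Uqcrfs1 and Cycs rose 2.43-fold, 2.38-fold and 2.25-fold, and Ndufa10 rose 1.95-fold. Relative to the median of all genes, the 3 lists stood at 1.17, 1.06 and 0.74. In the same libraries the median of mesothelial markers was -2.08 and that of macrophage markers -1.38.

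Genes of lipid synthesis and storage also rose. In fatty acid and triglyceride synthesis, 16 of 25 genes rose and 1 fell (18 and 1 adjusted over the list alone), with a median of 1.02 (camera adjusted p = 4.18e-07, but adjusted p = 0.566 with an estimated correlation). Acacb, the mitochondrial acetyl-CoA carboxylase, rose 4.13-fold, Me1, the cytosolic malic enzyme, 3.80-fold to 2900 CPM, Gpd1, glycerol-3-phosphate dehydrogenase, 3.28-fold, and Mogat2, a monoacylglycerol acyltransferase, 9.66-fold to 109.1 CPM. Scd1 of the same list had a log2 fold change of -0.85 and did not pass the edgeR test (SE 0.34, adjusted p = 0.108), but passed by DESeq2 (adjusted p = 0.011). In cholesterol synthesis, 12 of 21 genes rose and 0 fell (13 and 0 adjusted over the list alone), with a median of 0.70 (camera adjusted p = 3.29e-05, but adjusted p = 0.566 with an estimated correlation). Insig1, Cyp51, Sc5d and Hmgcs1 rose 2.80-fold, 2.41-fold, 2.16-fold and 1.98-fold. In lipolysis and the lipid droplet, 10 of 21 genes rose and 3 fell (11 and 4 adjusted over the list alone), with a median of 0.62 (camera adjusted p = 0.0257, but adjusted p = 0.566 with an estimated correlation). The droplet proteins Cidea, Plin5 and Plin2 rose 13-fold, 6.58-fold and 3.10-fold. In fatty acid uptake, 5 of 14 genes rose and 3 fell (7 and 3 adjusted over the list alone), with no call for the set (median 0.52, camera adjusted p = 0.236). The transporter Slc27a1 and the binding protein Fabp5 rose 2.23-fold and 2.08-fold, and Got2, the mitochondrial aspartate aminotransferase, and Lmf1, a lipase maturation factor, fell 3.11-fold and 2.39-fold. Of 20 adipocyte markers, 5 rose and 0 fell, as when adjusted over the list alone, with a median of 0.34 (camera adjusted p = 0.0201, but adjusted p = 0.566 with an estimated correlation). That median became 0.12 with library size alone, but lay 0.386 above the median of all genes before and 0.394 after. Pnpla2, the triglyceride lipase, Cidec and Slc2a4, the insulin-regulated glucose transporter, rose 1.91-fold, 1.84-fold and 2.17-fold, with the Cidec call ending without f/f replicate 2 (edgeR adjusted p = 0.0587) and on the FPKM scale (0.146). The adipocyte marker call ended without f/f replicate 3 (median 0.22, camera adjusted p = 0.0867) and without FKO replicate 1 (0.17, camera adjusted p = 0.0501), within a range of 0.00921 to 0.566 over all alternatives, and the lipolysis call without f/f replicate 2 (0.57, camera adjusted p = 0.0591) or f/f replicate 3 (0.52, camera adjusted p = 0.0632), within 0.011 to 0.566. These lists moved with lower markers of other cells, whose medians were -2.08 for mesothelium and -1.50 for progenitors and fibroblasts.

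Of 18 thermogenic genes tested, 8 rose and 0 fell (9 and 4 adjusted over the list alone), with a median of 0.92 (camera adjusted p = 0.0111, but adjusted p = 0.566 with an estimated correlation). Ppargc1a, a coactivator of mitochondrial biogenesis, rose 4.98-fold from 6.14 ± 2.18 CPM (SD, n = 3) to 30.5 ± 0.83 CPM (SD, n = 2), and Gk, glycerol kinase, rose 3.16-fold. Among 29 genes of insulin signalling and glucose use, 11 rose and 2 fell (13 and 3 adjusted over the list alone), with a median of 0.26 (camera adjusted p = 0.00847, but adjusted p = 0.566 with an estimated correlation). That median became 0.046 with library size alone, but lay 0.311 above the median of all genes before and 0.319 after. Ppp1r3c, a glycogen-targeting phosphatase subunit, rose 3.89-fold, and the glycolytic enzymes Pfkp and Pkm rose 3.11-fold and 3.08-fold. Among 32 genes of autophagy and the lysosome, 7 rose and 1 fell (12 and 2 adjusted over the list alone), with a median of 0.29 (camera adjusted p = 0.0151, but adjusted p = 0.566 with an estimated correlation). Library size alone took the autophagy median to 0.063, which lay 0.335 above the median of all genes before and 0.336 after. The autophagy receptor Sqstm1, the lysosomal protease Ctsd and the membrane protein Lamp1 rose 2.23-fold, 1.88-fold and 1.82-fold, and the stress protein Sesn2 fell 1.71-fold. The Ctsd call ended in 6 of 14 alternatives, among them without f/f replicate 1 (edgeR adjusted p = 0.0537), without f/f replicate 2 (0.0717), with library size alone (0.0747) and on the FPKM scale (0.104). AMPK and energy sensing was not called as a set (4 of 20 genes higher and 5 lower, also adjusted over the list alone, median 0.22, camera adjusted p = 0.424). Its median became -0.0019 with library size alone, but lay 0.27 above the median of all genes before and after. Within it, Prkaa2 and Prkaa1, the catalytic subunits of AMPK, rose 3.41-fold and 1.95-fold, Nampt of NAD synthesis rose 2.65-fold, and Ddit4, an mTORC1 inhibitor, fell 3.35-fold. The macrophage marker median was -1.38 in the same comparison.

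Markers of several other cell types and of the extracellular matrix were lower in FKO. All 11 mesothelial markers tested fell by edgeR, as when adjusted over the list alone (11 by DESeq2 and 6 by limma-voom), with a median of -2.08 (camera adjusted p = 5.44e-05, but adjusted p = 0.566 with an estimated correlation). Msln, mesothelin, was 4.53-fold lower, at 15.1 ± 3.59 CPM in f/f (SD, n = 3) and 3.32 ± 0.27 CPM in FKO (SD, n = 2), and Upk3b, Gpm6a and Upk1b were 4.42-fold, 4.23-fold and 3.75-fold lower. Of 24 progenitor and fibroblast markers, 14 fell and 1 rose (17 and 1 adjusted over the list alone), with a median of -1.50 (camera adjusted p = 3.95e-05, but adjusted p = 0.566 with an estimated correlation). Dpp4, Col1a2, Gsn and Col3a1 fell 5.20-fold, 4.74-fold, 2.86-fold and 2.79-fold. Gsn stood at 12027 ± 380 CPM in f/f (SD, n = 3), against 214.7 CPM for Col1a2, so it was not a trace transcript in these libraries. Of 25 macrophage markers, 14 fell and 1 rose (16 and 1 adjusted over the list alone), with a median of -1.38 (camera adjusted p = 2.86e-05, but adjusted p = 0.566 with an estimated correlation). Lyz1, C1qb, Csf1r and Mrc1 fell 5.54-fold, 3.73-fold, 2.86-fold and 2.77-fold. The riser was Lpl, a lipase that adipocytes express strongly, at 11129 CPM in f/f and 20782 CPM in FKO, named here after its values were seen. Its call ended in 6 of 14 alternatives, among them without f/f replicate 1 (edgeR adjusted p = 0.058), without f/f replicate 2 (0.0757), with library size alone (0.0656) and on the FPKM scale (0.14). Of 34 genes of the extracellular matrix and fibrosis, 16 fell and 0 rose (17 and 0 adjusted over the list alone), with a median of -1.12 (camera adjusted p = 2.12e-05, but adjusted p = 0.566 with an estimated correlation). Thbs1, thrombospondin 1, fell 5.28-fold from 2590 ± 22.9 CPM (SD, n = 3) to 491.1 ± 159 CPM (SD, n = 2), the collagen-crosslinking enzymes Lox and Loxl1 fell 5.24-fold and 4.10-fold, and Tgfbi fell 3.24-fold. Of 29 cytokine and chemokine genes, 12 fell and 3 rose (17 and 3 adjusted over the list alone), with a median of -1.08 (camera adjusted p = 0.00186, but adjusted p = 0.566 with an estimated correlation). The chemokines Ccl6 and Ccl2 fell 5.32-fold and 2.87-fold, the macrophage growth factor Csf1 fell 3.24-fold, and the acute-phase gene Orm1 rose 2.89-fold.

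Other marker lists were not called as sets, though without f/f replicate 1 the endothelial list (median -0.41, camera adjusted p = 0.0246) and the pericyte and smooth muscle list (-0.79, camera adjusted p = 0.0224) were called lower. Of 17 endothelial markers, 1 fell and 0 rose, also adjusted over the list alone (median -0.32, camera adjusted p = 0.236); it was Lyve1, a lymphatic and macrophage receptor, 5.53-fold lower, while Esam, Cldn5 and Erg had log2 fold changes of -0.54, -0.88 and 0.52 that did not pass the edgeR test. Esam passed with library size alone (edgeR adjusted p = 0.04) and on the FPKM scale (0.0476), Cldn5 by DESeq2 (0.0345) and Erg without f/f replicate 3 (0.0227). Of 13 pericyte and smooth muscle markers, 4 fell and 1 rose (5 and 1 adjusted over the list alone, median -0.53, camera adjusted p = 0.161). Acta2, Tagln and Rgs5 fell 3.71-fold, 4.09-fold and 1.64-fold, and the proteoglycan gene Cspg4 rose 5.90-fold to 286.4 CPM. Of 6 T and NK cell markers, 1 fell, also adjusted over the list alone (Cd2, 3.50-fold lower, list median -1.13, camera adjusted p = 0.117). Of 7 B cell markers, 1 fell (Bank1, 2.91-fold lower) and 0 passed when adjusted over the list alone (median -0.67, camera adjusted p = 0.358). Of 10 neutrophil and mast cell markers, 2 fell and 1 rose, also adjusted over the list alone (median -1.29, camera adjusted p = 0.176). The Bank1 call ended in 7 of 14 alternatives, among them without f/f replicate 1 (edgeR adjusted p = 0.0814), without f/f replicate 3 (0.083), with limma-voom (0.0934) and on the FPKM scale (0.0706). The changed neutrophil and mast cell markers were Mmp9, 6.45-fold lower, Tpsb2, a mast cell tryptase with 0 counts in FKO, and Kit, 1.88-fold higher. Of 6 skeletal muscle markers, 1 rose, also adjusted over the list alone (Mb, 1.01 CPM in FKO, within a gene overlapped by Apol6), and the list median of -0.40 differed in sign from the camera direction, which was up (adjusted p = 0.932). Epididymis and testis markers were too few for a set test, with 2 tested (Crisp1 lower, Rnase10 higher at 0.71 CPM) and a list median of -3.76, or -1.76 with Crisp1 at its bound. Of 4 erythroid markers, 0 changed by edgeR at an adjusted or unadjusted p under 0.05, and 0 by DESeq2 or limma-voom. Counts of near-identical globin copies swapped between libraries, and their sums, chosen after the values were seen, were lower at an unadjusted but not at an adjusted p under 0.05. Hba-a1 and Hba-a2 together had a log2 fold change of -0.645 (edgeR adjusted p = 0.0701), and the beta-globin copies together -0.665 (edgeR adjusted p = 0.0549). Without f/f replicate 1 the call of Mmp9 ended (edgeR adjusted p = 0.0581), without f/f replicate 2 those of Rgs5 and Mb (0.0615 and 0.0546), and without f/f replicate 3 that of Cd2 (0.0517). With limma-voom those of Mmp9 and Tagln ended (adjusted p = 0.119 and 0.0834), on the FPKM scale those of Mmp9, Tagln and Kit (0.071, 0.0509 and 0.0744), and with library size alone that of Kit (0.0509).

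Stress and early response genes moved in part. Of 21 immediate early genes, 9 fell and 0 rose (11 and 0 adjusted over the list alone), with a median of -0.71 (camera adjusted p = 0.00296, but adjusted p = 0.566 with an estimated correlation). Btg2, Zfp36, Nr4a1 and Dusp1 fell 2.28-fold, 2.01-fold, 1.94-fold and 1.87-fold. The call ended without FKO replicate 2 (median -0.52, camera adjusted p = 0.0773), within a range of 0.000107 to 0.566. In the same libraries the marker medians were -2.08 for mesothelium, -1.50 for progenitors and fibroblasts and -1.38 for macrophages. Of 22 p53 target genes, 7 fell and 1 rose, also adjusted over the list alone, with no call for the set (median -0.35, camera adjusted p = 0.358). Cdkn1a, the p21 cell cycle inhibitor, fell 3.38-fold and Pmaip1 fell 2.63-fold. Genes of the unfolded protein and integrated stress responses went both ways (5 of 26 higher and 5 lower, 7 and 6 adjusted over the list alone, camera adjusted p = 0.236), with a median of 0.16. That median became -0.069 with library size alone, but lay 0.21 above the median of all genes before and 0.20 after, and it became -0.056 on the FPKM scale. Chac1, Dnajb9 and Psat1 rose 3.72-fold, 3.57-fold and 2.49-fold. Of 22 interferon response genes, 1 rose, also adjusted over the list alone (median -0.23, camera adjusted p = 0.951), while Ifi27l2a, Oasl2 and Oas1a had log2 fold changes of 1.10, -1.09 and -1.16 that did not pass the edgeR test but passed by DESeq2 (adjusted p = 0.0122, 0.0277 and 0.0468). Of 28 cell cycle genes, 1 rose and 2 fell (Ccne1 2.03-fold higher, E2f1 and Mcm3 2.90-fold and 1.81-fold lower; 1 and 0 adjusted over the list alone; median -0.19, camera adjusted p = 0.424), and the median turned to 0.024 without f/f replicate 3. Without f/f replicate 2 or 3 the calls of E2f1 (edgeR adjusted p = 0.0605 and 0.0547) and Mcm3 (0.0524 and 0.0584) ended, and that of E2f1 also with limma-voom (0.0504).

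Among 26 RNA binding and splicing proteins that arginine methyltransferases modify, 1 rose and 3 fell (1 and 2 adjusted over the list alone), with no call for the set (median 0.040, camera adjusted p = 0.916). Hnrnpu rose 1.79-fold, and Cirbp and Rbmx fell 1.81-fold and 1.59-fold, with the Rbmx call ending without f/f replicate 1 or 3 (edgeR adjusted p = 0.0859 and 0.0686). The list median became -0.090 with upper-quartile factors and -0.19 with library size alone, but lay 0.087 above the median of all genes before and 0.083 and 0.082 above it after; the list mean was -0.042. Of 40 cytosolic ribosomal protein genes, 0 changed by edgeR, also adjusted over the list alone (7 lower at an unadjusted p under 0.05, 3 lower by DESeq2 and 0 by limma-voom), yet the set was called lower (median -0.23, camera adjusted p = 0.0257, but adjusted p = 0.739 with an estimated correlation). Rps20, Rpl35, Rplp1 and Rps16 had log2 fold changes of -0.52, -0.57, -0.51 and -0.45. The ribosomal call ended without f/f replicate 1 (camera adjusted p = 0.111), f/f replicate 3 (0.0889), FKO replicate 1 (0.0505) or FKO replicate 2 (0.255), among other settings, within a range of 0.000451 to 0.739. The macrophage marker median was -1.38 and the mesothelial one -2.08 in the same libraries. Altogether camera with its preset correlation called 17 of 31 lists, 10 higher and 7 lower. These are not all separate results, since lists share genes. Of the genes fixed per list, 11 of 21 adipocyte markers, 9 of 21 lipolysis genes and 8 of 22 thermogenic genes stand in other lists too. With an estimated correlation camera called 0 lists, at an adjusted or an unadjusted p under 0.05 (smallest adjusted p = 0.566). The test fry, which asks whether a set moves on balance in one direction, called 5 (18 unadjusted). Of these 5 adjusted calls, 5 were higher and 0 lower: thermogenic genes, fatty acid oxidation, lipolysis, TCA cycle and autophagy. The other lists that camera called higher had a fry adjusted p of 0.0519 to 0.0532. Those that camera called lower had 0.0522 to 0.0804, apart from 0.254 for ribosomal proteins. The split by direction thus rests mostly on values near the threshold.

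**Figure D3:**
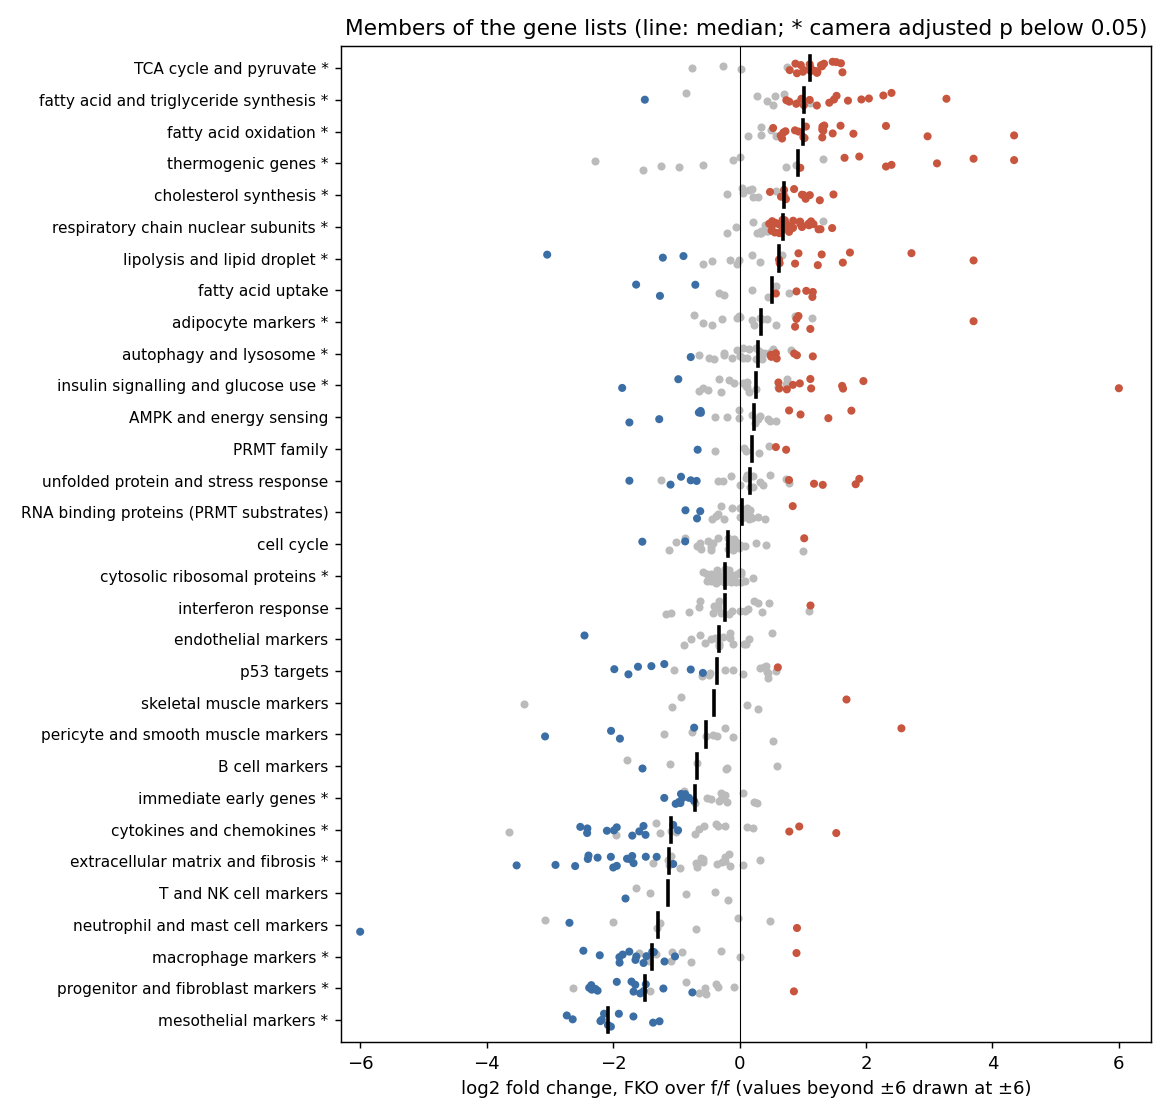
Log2 fold change of FKO over f/f for each tested member of 31 gene lists, with red and blue points for members called higher and lower, grey points for the rest and a line at the median. The TCA cycle list lies highest, with a median of 1.12, and the mesothelial list lowest, with -2.08.

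The last comparison asked whether genes changed the share of their transcripts. Tns1, a focal adhesion protein, had 87.1 ± 1.75% of its estimated counts on NM_027884 in FKO (SD, n = 2) and 0.0201 ± 0.00326% in f/f (SD, n = 3), although the total did not pass the edgeR test (adjusted p = 0.137). Ndst1, a heparan sulfate modifying enzyme, had 97.6 ± 1.80% on NM_008306 in f/f (SD, n = 3) and 39.6 ± 4.26% in FKO (SD, n = 2). Fam213a, a redox protein, had 13.8 ± 3.39% on NM_001316740 in FKO (SD, n = 2) and 0.90 ± 0.41% in f/f (SD, n = 3). Mfn2, a mitochondrial fusion protein, had 6.19 ± 0.94% on NM_001285921 in FKO (SD, n = 2) and 0 counts there in f/f, which allows a share of up to 0.00564%. Chtop, a chromatin protein that binds PRMT1, had 15.1 ± 10.8% on NM_001293782 in f/f (SD, n = 3) and 0 counts there in FKO, which allows up to 0.0409%. Transcript use changed in 40 of 3997 genes (edgeR diffSpliceDGE with Simes p-values, adjusted; 263 unadjusted), 14 of which also changed in total, and that of Prmt1 did not (edgeR adjusted p = 1). Transcript counts are estimates whose assignment error is not in the test, and 22 genes passed when only transcripts with at least 10% of their gene's counts were kept, 17 of them among the 40, while the gene-level test called 227. Under that filter the calls of Fam213a and Chtop ended (edgeR adjusted p = 1 for each, the highest over their alternatives, with 6.47e-07 and 8.3e-09 the lowest). The filter removed the transcripts named for them, NM_001316740 and NM_001293782, so it did not test whether those changed. The calls of Tns1 and Ndst1 had a highest edgeR adjusted p over their alternatives of 0.162 and 0.209. Of the 40 genes, 9 passed again without FKO replicate 1 and 8 without FKO replicate 2, where 32 and 30 genes were called, and the 5 named genes were among those that passed in both cases.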

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

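Library size alone was chosen after seeing the data; the other settings were planned. The 3674 called genes became 1497 when 21215 transcripts were tested one by one, where the cause was not tested, 2132 with a 2-fold threshold, which removes genes by construction, and 909 to 3449 with 1 library left out, where the lowest 2 leave 1 FKO library that is assumed to vary like the f/f libraries. All other counts lay between 2726 and 4864. Of 1869 tests of called genes under alternatives, 1706 stayed past the threshold with the same sign, 163 fell short and 0 changed sign. Of genes that the rule picked or that were singled out, and of lists, that were not called, 44 tests of genes and 3 of lists passed the threshold with the same sign. The Prmt1 log2 fold change lay between -0.89 and -0.60 in all settings and between -0.72 and -0.60 with 1 library left out. Camera called 14 to 18 lists with 1 f/f library left out and 17 in each setting that kept all libraries, against 0 with an estimated correlation and 5 with fry. The estimated correlation was above the preset of 0.01 in every called list but the thermogenic one (-0.026), and reached 0.818 for mesothelial markers. A higher correlation raises the variance that camera gives a set, which weakens the calls of those lists by construction. The cause of the fry count was not tested. Against 40 genes with changed transcript use, 22 were called with the stricter filter, where fewer transcripts were tested (17 shared; Mfn2 was not tested there), 227 by the gene-level test (40 shared), and 30 to 55 with 1 library left out (8 to 28 shared). The cause of the gene-level count was not tested. Nothing says that equal replicate numbers pair the libraries: deviations of same-numbered samples correlated at 0.0657 and -0.0812. With the replicate block 3278 genes, 17 lists (16 shared) and 3 genes with changed transcript use (3 shared) were called. Replicate 3 of f/f has no FKO library with its number. The block therefore takes it out of the genotype estimate by construction and leaves fewer degrees of freedom. How much of the change this explains was not tested. The block ended the calls of the ribosomal list (median -0.17, camera adjusted p = 0.156), of transcript use in Tns1, Ndst1 and Fam213a (edgeR adjusted p = 0.162, 0.209 and 0.209), and of Prmt9, Cd2, Bank1, Rnase10 and Mb among named genes (0.0571, 0.0765, 0.0862, 0.079 and 0.122). It added that of the neutrophil and mast cell list (median -1.07, camera adjusted p = 0.0422). Among named genes it added Ifi27l2a, Erg and Scd1 (log2 fold change 1.49, 0.72 and -1.08, edgeR adjusted p = 0.00801, 0.0283 and 0.0331). Depth limits genes near the floor of 3 counts.

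Signs reversed in results that were not called. Upper-quartile factors and library size alone shift all genes together by construction, which moved the median of all genes from -0.048 to -0.17 and -0.27 and took the values printed for them past 0; for the other settings the cause was not tested. With library size alone, log2 medians or values were -0.016 for the PRMT family, -0.001935 for AMPK, -0.069 for stress responses, -0.19 for RNA binding proteins, -0.15 for Prmt3 and -0.12 for Prmt7. With limma on log2(FPKM + 1) they were -0.005454 (PRMT family), -0.056 (stress), -0.17 (RNA binding), -0.12 (Prmt3), -0.10 (Prmt7) and 0.67 (Hba-a2). With upper-quartile factors they were -0.090 (RNA binding), -0.056 (Prmt3) and -0.022 (Prmt7). The block gave 0.005234 (cell cycle) and 7.36 (Hba-a2, past the threshold at an edgeR adjusted p = 0.028), and limma-voom 0.74 (Hba-a2). With 1 library left out, values ran from -0.99 to 0.042 (skeletal muscle, positive without f/f replicate 2 or 3), -0.36 to 0.024 (cell cycle, positive without f/f replicate 3), -0.036 to 0.075 (RNA binding, negative without f/f replicate 2), -0.037 to 0.19 (Prmt3, negative without f/f replicate 2 or FKO replicate 1), -2.61 to 0.13 (Cd79b, positive without FKO replicate 2), -5.62 to 0.30 (Hba-a1, positive without FKO replicate 2) and -8.60 to 8.07 (Hba-a2, positive without f/f replicate 3 or FKO replicate 1).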

Other observations

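All tests in this part, and the 6 lists and the genes of its first paragraphs, were chosen after the data were seen, so they are no independent evidence of direction.

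Of 38 tested genes for antioxidant and detoxification enzymes, 29 were called higher in FKO and 1 lower (median log2 fold change 1.19, camera adjusted p = 7.25e-12, adjusted p = 0.143 with an estimated correlation, fry adjusted p = 0.00328 over 6 added lists). Cbr1 (2.98, SE 0.18), Nqo1 (2.89, SE 0.40), Gsta3 (2.74, SE 0.21) and Gclm (2.31, SE 0.25), which encode carbonyl, quinone and glutathione enzymes, were higher in 2 of 2 FKO libraries than in any f/f library, and Gpx3, a secreted glutathione peroxidase, was lower (-1.47). Keap1, the adaptor that marks the antioxidant factor NRF2 for degradation, was lower (-0.92, SE 0.14, edgeR adjusted p = 0.00643). In the pentose phosphate pathway, a source of NADPH, 4 of 7 genes were higher and 0 lower (camera adjusted p = 0.0021, adjusted p = 0.143 with an estimated correlation, fry adjusted p = 0.00113), with Pgd at 2.35 and Tkt at 1.70. Breakdown of branched-chain amino acids had 8 of 21 genes higher and 0 lower (camera adjusted p = 8.06e-05, adjusted p = 0.33 with an estimated correlation, fry adjusted p = 0.0401), and peroxisomal genes 14 of 30 higher and 1 lower (camera adjusted p = 8.06e-05, adjusted p = 0.173 with an estimated correlation, fry adjusted p = 0.00905). In the same libraries the macrophage marker median was -1.38 and the mesothelial one -2.08.

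Of 18 complement genes, 12 were lower and 1 higher (median -1.62, camera adjusted p = 0.000414, adjusted p = 0.143 with an estimated correlation, fry adjusted p = 0.0029), beside medians of -1.38 for macrophage and -1.50 for progenitor and fibroblast markers; 5 of the 18 stand in the fixed lists, among them C1qb as a macrophage marker. C4b was at -3.14 (SE 0.17), and Serping1, the inhibitor of C1, at -2.57, while Masp1 was higher (2.48). Of 26 imprinted genes, 10 were lower and 5 higher, with no call by camera (median -0.51, adjusted p = 0.129, 0.275 with an estimated correlation) but one by fry (adjusted p = 0.004). Mest fell from 785, 884 and 670 CPM in f/f to 39.4 and 43.8 CPM in FKO, Klf14, encoded near it, from 9.40, 12.8 and 14.4 to 0.42 and 0.52 CPM, and Peg3 had a log2 fold change of -2.05, while Peg10 was at 0.96, a call that ended in 6 of 14 alternatives, among them without f/f replicate 1 (edgeR adjusted p = 0.0778) and without f/f replicate 3 (0.0781). Nnt, the mitochondrial transhydrogenase that carries a deletion in C57BL/6J but not in C57BL/6N mice, was at 51.3, 30.0 and 61.5 CPM in f/f and 9.82 and 10.7 CPM in FKO (log2 fold change -2.21, SE 0.31, edgeR adjusted p = 0.00464). The labels give C57BL/6N for the mice; a difference of substrain between the groups, for example from the Cre line, was not tested here and stays open.

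Markers of mesothelium, macrophages, progenitors and matrix were lower in FKO. Their f/f means included 15.1 CPM for Msln, 146 CPM for Csf1r, 214.7 CPM for Col1a2, 2590 CPM for Thbs1 and 12027 CPM for Gsn. Means in f/f above 100 CPM were found in 0 of 11 mesothelial and 4 of 17 endothelial markers. They were also found in 9 of 25 macrophage markers, 6 of 24 progenitor and fibroblast markers and 18 of 34 matrix genes. A lower share of all non-adipocyte cells alike would lower their markers by about the same amount. The median of the 16 endothelial markers that stand in no other list was -0.295. It lay 1.79 above that of 11 mesothelial markers (-2.08, permutation test over genes, 2-sided, p = 7e-04). The permutation takes genes as independent, whereas markers of a list varied together (estimated correlation 0.645 in the endothelial and 0.818 in the mesothelial list). Its p thus leaves out the spread between libraries. The pair was also picked after the medians were seen. Among the lists of other cell types given a set test, these are the lowest and the one closest to 0. The medians of the others ran from -1.50 (progenitors and fibroblasts) to -0.40 (skeletal muscle). Because the pair was picked for its gap, the p does not decide the question. The choice among the 4 scalings run did not make the direction, since the list median closest to 0 was -1.11 and the upper quartile closest to 0 was -0.56; a scaling outside these was not tested. Carry-over of particular cells into some preparations may contribute, since these markers had a median log2 range of 1.04 among the f/f libraries; it cannot be told apart from an effect of genotype on those cells, because each genotype has its own preparations, so both stay open.

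Genes of the TCA cycle, fatty acid oxidation and the respiratory chain were higher in FKO. A higher share of adipocyte RNA alone would raise adipocyte markers as much, but the median of 104 energy genes lay 0.47 above that of 20 adipocyte markers (0.81 against 0.34, permutation test over genes, 2-sided, p = 3e-04). That test takes genes as independent, whereas genes of these 3 lists varied together (estimated correlation 0.606, 0.341 and 0.597 in the same order). Its p therefore does not measure the spread between libraries. After removal of the trend of fold change on transcript length, the lowest of the 3 list medians was 0.85, and over the 4 scalings run the list median closest to 0 was 0.47, with the closest lower quartile at 0.28. A change within adipocytes is a candidate explanation that these tests leave open, as is any other difference between the 2 sets of mice, which was not tested.

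Sap18b fell and Sap18 rose from 17.4 to 18.8 CPM in f/f to 80.9 and 82.5 CPM in FKO. The log2 fold change of their sum was -0.027 (SE 0.14), where loss of Sap18b alone would give -2.21, consistent with counts divided differently between copies, since 98.8% of the 31-base words of Sap18b also occur in Sap18. For the sum of Npcd, Nptxr and Cbx6 it was 0.053 (SE 0.17), which decides nothing, since loss of Npcd alone would give only -0.16. Globin copies showed such swaps between libraries of 1 group, with Hba-a1 at 190, 180 and 4.40 CPM and Hba-a2 at 0.24, 0.19 and 261 CPM in f/f. Why the division followed genotype for Sap18 is open, and a sequence variant near 1 copy was not tested.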
